A study of Mus musculus with 6 samples.

How the data were processed

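Kidney RNA of 6 libraries from female C57BL/6J mice was measured, 3 after instillation of uropathogenic E. coli strain 536 into the bladder and 3 after instillation of phosphate-buffered saline. RNA had been isolated with the NucleoSpin RNA kit and libraries made with the Lexogen QuantSeq 3' mRNA kit, per the labels' protocols. The deposited values are raw read counts per mouse Ensembl gene, whole numbers whose totals differ between libraries. The submitters' processing notes name cutadapt (adapter trimming), STAR (alignment) and featureCounts (counting per gene), without versions, and the genome builds GRCm38 and GRCh38 without their roles. GRCh38 is a human build, and all gene identifiers in the table are mouse identifiers. The annotation release, the strand setting of the counting and the use of molecular identifiers are not given in the sources used here. Without molecular identifiers, PCR copies count as reads, so counting intervals and floors cover counting error only. Reads of near-identical genes, such as Saa1 and Saa2, the globin genes or Acaa1a and Acaa1b, can be lost or divided, depending on how the authors treated reads with several positions.

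Gene symbols came from the reference table, which matched 54409 of the 54532 identifiers, and where a symbol had several identifiers the one with most reads was used. Coordinates are 1-based GRCm38 positions of whole genes in the GENCODE M21 annotation, and the genes given with coordinates are all protein coding. Groups came from the labels. The library numbers in the titles of the groups have none in common. A deposited table also numbers the libraries of each group from 1 to 3 in list order, which names no shared animal, day or batch, so no pairing was used. Pairs of libraries were compared by a chi-square over genes with at least 20 reads, and all pairs differed by 5.87 or more per degree of freedom, so no library was counted as a copy of another.

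The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts of all 6 libraries, with group as the single term. Genes were kept by filterByExpr with a minimum count of 10, which left 14154, libraries were scaled by TMM, and dispersions were estimated with the robust option. P-values are 2-sided and adjusted by Benjamini-Hochberg over all tested genes, and a gene was called, and said to rise or fall, at an adjusted p of at most 0.05. Log2 fold changes are UTI minus control with a prior count of 0.125, their standard error is the size of the change divided by the square root of F, and CPM are TMM-scaled. Tested on simulated counts for this comparison with 14154 genes, the procedure recovered 37 of 100 planted changes of 1 and 89 of 100 of 2 on the log2 scale, with 10 false among 136 calls. So 2-fold changes were often missed at this depth and replication, with a biological coefficient of variation of 0.244. Depth of 6541230 to 10490107 counts puts a floor of 3 counts at 0.286 to 0.459 CPM in a library. For genes with 0 reads in controls a fold was computed against 3 counts over the group, and for genes with 1 to 3 reads the ratio is given with an exact 95% counting interval.

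Before the data were examined, 31 gene lists were written, 12 for the comparison itself and 19 for other cell types and RNA quality, and the 29 with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over these lists. Camera called 9 lists up and 9 down. With a correlation estimated for each list, the acute phase and neutrophil lists alone held. In simulated data with 30 random lists 0 were called and a list of 20 genes planted at -1 was called. The simulated genes varied independently of each other, so this does not check false calls of lists whose genes vary together. The comparison and its test, the alternatives and the rule for named genes were fixed at the same time, and the tests of technical explanations were written later, after the called genes were known. The rule took, among called genes of at least 5 CPM on average with a symbol that is not a clone model and no overlap between groups, the 12 largest rises and 12 largest falls; the 3 members of smallest p in each of the 12 main lists and the 2 most abundant in each other list; and a fixed set whatever its values, with Lcn2, Havcr1, Srebf2, Abca1, Apoe, Tlr4, Il6 and Umod in it. Some genes that the rule takes are not reported here. Other list members that are named were chosen after their values were seen.

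The alternatives were DESeq2 size factors in edgeR, library totals alone, totals without mitochondrial genes or without the 50 most abundant genes, no low-count filter, a filter of over 5 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, edgeR without the robust option, glmTreat against a minimum log2 change of 1, an adjusted p of 0.01, each library left out in turn, and for lists camera with estimated correlations and fry. Thinning all libraries to the smallest total, and 7 further lists, were added after the data were examined. A sign change counted as a reversal where either fit called the result. Figures were drawn with matplotlib 3.10.9. A table that repeats the assignment of libraries to titles was not used.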

Results

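Kidney RNA was profiled in female mice of the inbred strain C57BL/6J after infection of the urinary tract. Uropathogenic E. coli strain 536 had been placed in the bladder in 2 instillations 3 h apart, and the kidneys were taken 16 h after the second. The 3 libraries of this group (UTI 12, UTI 13 and UTI 14) were compared with 3 libraries from mice given phosphate-buffered saline through the urethra (control 15, control 19 and control 20). The labels number the libraries but do not state that each is a separate mouse, so p-values measure the spread between these libraries. Reads of the 3' mRNA kit come from the 3' ends of polyadenylated transcripts, and the deposited values were raw counts per gene. The counts summed to 10490107 in control 15, 9268861 in control 19 and 9302939 in control 20, and to 6667339 in UTI 12, 7180714 in UTI 13 and 6541230 in UTI 14. The mean total was 9687302 ± 695458 (SD, n = 3) in controls and 6796428 ± 338722 (SD, n = 3) in UTI, with no overlap, and an exact permutation test (2-sided) gave p = 0.1, the smallest that 3 against 3 libraries allow. Between 19410 and 20794 genes had at least 1 read per library. Mitochondrially encoded genes took 16.0% to 19.9% of a library's counts, and Gm42418, a locus known to overlap ribosomal RNA sequence, took 10.3% to 13.3%.

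Control 19 stood apart from the other 5 libraries. The first principal component of log2 CPM carried 47.2% of the variance and placed control 19 at 80.2, with the others between -27.2 and 0.0755. The second component carried 23.6% and placed the 3 UTI libraries between 9.88 and 35.9, control 19 at 12.9, and control 15 and control 20 at -37.5 and -32.2. Spearman correlations across genes were 0.932 and 0.942 between control 19 and the other controls, 0.981 between control 15 and control 20, and 0.974 to 0.982 among the UTI libraries.

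**Figure D1:**
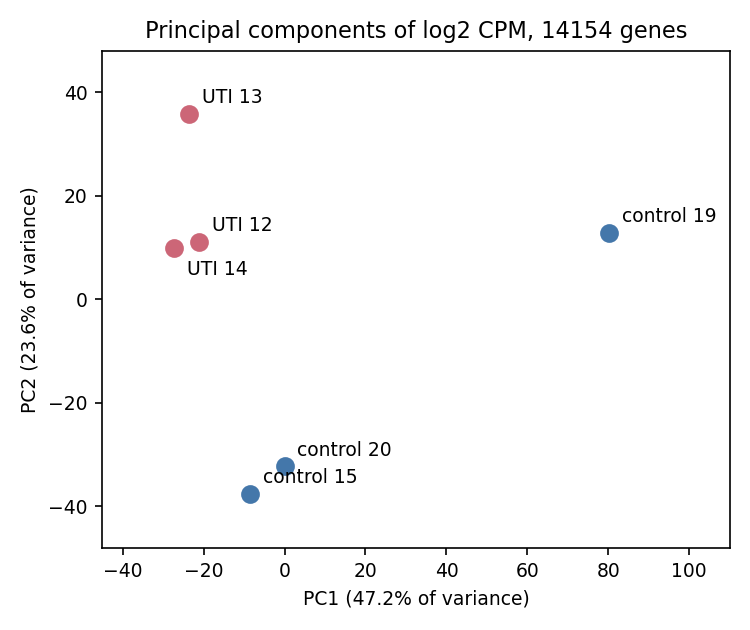
First and second principal components of log2 CPM over 14154 genes, in arbitrary units, with a point for each kidney library (blue, control; red, UTI). Control 19 lies at 80.2 on the first component, and the other libraries lie between -27.2 and 0.0755.

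The series title concerns pyelonephritis, serum cholesterol and atherosclerosis, and the comparison asks which kidney transcripts differed after infection, those of cholesterol metabolism among them. Acute phase genes, whose products in plasma increase in inflammation, were among those with large rises: Fgg was 25.3-fold higher in UTI, Fga 20.5-fold and Saa1 470-fold, the last from 4 reads over the 3 controls. Lcn2, which encodes the iron-sequestering neutrophil gelatinase-associated lipocalin, was 44.0-fold higher, and Havcr1, which encodes kidney injury molecule 1 of damaged proximal tubules, was 22.7-fold higher. Genes that fell included Cpne4 (log2 fold change -2.56 ± 0.29, SE), Car3, which encodes carbonic anhydrase 3 (-2.41 ± 0.22), and Sectm1b (-1.96 ± 0.29). Genes of cholesterol synthesis and uptake that fell included Nsdhl, Msmo1 and Insig1.

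Of 14154 genes tested, 157 were called at an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 78 higher and 79 lower in UTI. Of these, 75 were higher and 55 lower by at least 2-fold, and 30 were higher by at least 8-fold against 0 lower. An unadjusted p under 0.05 was reached by 1720 genes. The 3 UTI and the 3 control values did not overlap for any of the 157 genes, nor for 20.02% of all tested genes, where chance gives 10%. Scaling by library totals alone, which moved the median gene up by 0.135 on the log2 scale, gave 94 higher and 48 lower genes, 66.2% higher against 49.7%. The count was 506 (222 higher, 284 lower) without control 19, 33 without control 20, and 53, 46 and 58 without UTI 12, UTI 13 and UTI 14, and DESeq2 called 345 genes. Of 8 neutrophil markers 2 rose, with a list median of 3.47 on the log2 scale, and camera called that list up together with the acute phase, cytokine, antimicrobial, interferon and injury lists. It also called up the Toll-like receptor and NF-kB, monocyte and macrophage, and immediate early and heat shock lists (camera adjusted p of 0.0635, 0.191 and 0.328 with an estimated correlation). With an estimated correlation the neutrophil and acute phase lists kept their calls, and the adjusted p was 0.0598 for cytokines, 0.0551 for antimicrobial genes, 0.0598 for interferon-stimulated genes and 0.0607 for injury. Of the 39 called genes that the naming rule picked, 22 were called in each of the 6 fits that left out 1 library. Exons of Fgg, Cp, Slpi, Spp1, Bcl3, Slc5a2, Dbp, Acaa1b, Plin4, Umod, Csf1r, Ndrg1, Aldoa, Hspa8, Rpl32, Akr1b7 and mt-Nd4 overlap other annotated genes, and without a stated strand setting the reads of such pairs cannot be told apart.

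Of 20 tested acute phase and complement genes, 10 rose and 0 fell, with a median log2 fold change of 2.08 (camera adjusted p = 1.02e-87, and adjusted p = 0.00311 with an estimated correlation), and 13 rose when adjusted over the list alone. The serum amyloid A genes lie together on chromosome 7 (GRCm38). Saa1 (ENSMUSG00000074115, positions 46740497 to 46742980) went from 0.141 ± 0.0436 CPM in controls to 74.9 ± 3.00 CPM in UTI (SD, n = 3; edgeR adjusted p = 6.67e-08). Its control level, 4 reads over the 3 controls, lies under the floor of 3 counts in a library, so the size of its fold change is uncertain. Saa2 had 0 reads over the 3 controls and 653 over the 3 UTI libraries, at least 283-fold higher against a floor of 3 counts over the group. Saa3 had 3 reads against 427, a ratio of 185 with a 95% counting interval of 62.9 to 901. Reads of Saa1 and Saa2, near-identical copies, may be shared between them. The 3 fibrinogen chain genes are neighbours on chromosome 3, and Fga (ENSMUSG00000028001, positions 83026076 to 83033627) went from 7.99 ± 1.75 to 164 ± 7.18 CPM (adjusted p = 2.36e-06, edgeR). Fgb rose by 4.29 ± 0.33 and Fgg by 4.66 ± 0.24 on the log2 scale (SE). Serpina10, a gene of the serpin family of protease inhibitors, rose by 4.43 ± 0.29. Lrg1, C3, Serpina3n and Osmr also rose, while Il6st (0.40 ± 0.14) and Cfb (-0.20 ± 0.28) did not pass the test. The calls of C3 and Serpina3n ended without UTI 12 or UTI 13, with adjusted p of up to 0.0662 and 0.104, and that of Osmr without control 20 or any UTI library, with an adjusted p of up to 0.204 (edgeR).

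Cxcl5 and Cxcl1, which encode chemokines that attract neutrophils, and the cytokine gene Il11 rose. Cxcl5 rose by 5.79 ± 0.79 on the log2 scale (SE), from 0.191 to 12.5 CPM, and Il11 by 3.02 ± 0.44. The control level of Cxcl5 rests on 6 reads, all in control 15. Cxcl1 had 3 reads over the controls and 93 over the UTI libraries, a ratio of 40.3 with a counting interval of 13.4 to 199. Of 13 tested cytokines and chemokines, 3 rose and 0 fell (median 3.02, camera adjusted p = 2.05e-17, and adjusted p = 0.0598 with an estimated correlation), and 9 rose when adjusted over the list alone. Among the others, Il1b had 3.68 ± 0.68 (adjusted p = 0.0756, edgeR). Il6 was too low to test, with 0 reads over the controls and 8 over the UTI libraries. Of 18 tested Toll-like receptor and NF-kB genes, 2 rose and 0 fell, Nfkbiz by 1.71 ± 0.22 and Bcl3 by 1.38 ± 0.27, while 13 rose when adjusted over the list alone (median 0.89, camera adjusted p = 3.81e-14, and adjusted p = 0.0635 with an estimated correlation). Tlr4, the receptor of bacterial lipopolysaccharide, had 2.05 ± 0.56 from 0.666 to 2.84 CPM and did not pass (edgeR adjusted p = 0.131), nor did Birc3 at 1.31 ± 0.34. The cytokine median was 2.001 without UTI 13, 1.34 over 7 genes under the stricter filter and 1.43 over 19 genes in DESeq2. The count was 0 without control 20 or UTI 13, 2 without UTI 12 and 6 without UTI 14 or without the robust option of edgeR. The Toll-like receptor and NF-kB count was 0 without control 20, 3 without control 19 and 1 with limma-voom or without any 1 of the UTI libraries. The calls of Cxcl1 and Il11 ended without control 20 or UTI 13 (edgeR adjusted p of up to 0.134 and 0.0662) and that of Cxcl5 without control 20, UTI 12 or UTI 13 (up to 0.0777). Of the 6 fits that left out 1 library, the call of Bcl3 was kept only in that without control 19 (up to 0.206), and that of Nfkbiz ended without control 20 (0.052).

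Lcn2 (ENSMUSG00000026822, chromosome 2, positions 32384633 to 32388252) went from 4.87 ± 3.01 to 218 ± 50.5 CPM (SD, n = 3; edgeR adjusted p = 0.00263). Cp, which encodes the copper-binding ceruloplasmin, went from 169 ± 0.787 to 514 ± 115 CPM, and Slpi, a protease inhibitor gene, had 2 reads against 65, a ratio of 42.3 with a counting interval of 11.2 to 356. These were the 3 of 11 tested antimicrobial and nutritional immunity genes that rose, and 0 fell (median 1.16, camera adjusted p = 4.44e-12, and adjusted p = 0.0551 with an estimated correlation), with 5 that rose when adjusted over the list alone. Defb1 (-0.41 ± 0.17) and Wfdc2 (0.23 ± 0.18) did not pass. Of 8 tested neutrophil markers, S100a8 (4.77 ± 0.45) and Fpr2 rose and 0 fell (median 3.47, camera adjusted p = 7.88e-14, and adjusted p = 0.0199 with an estimated correlation), and 6 rose and 1 fell when adjusted over the list alone. S100a9 had 4.30 ± 0.76 without passing (adjusted p = 0.0837, edgeR). The count was 4 with DESeq2 size factors, library totals alone or totals without the 50 most abundant genes, and DESeq2 called 10 higher and 1 lower of 15 markers. The neutrophil count was 7 risen and 1 fallen without control 19, where 15 markers passed the low-count filter. It was 1 risen without control 20 (15 tested), UTI 12 (10 tested) or UTI 13 (8 tested), where the call of Fpr2 ended (edgeR adjusted p of up to 0.0763). The call of Slpi also ended without these 3 libraries (adjusted p of up to 0.119, edgeR), and the antimicrobial count was 5 without control 15 or control 19 (median 0.60 without control 19) and 2 without control 20, UTI 12 or UTI 13. Under the stricter filter, 2 of 6 antimicrobial genes rose, with a median of 0.37, and 1 of 4 neutrophil markers, with a median of 2.14. Of 17 monocyte and macrophage markers, 1 rose, Chil3, and 0 fell (median 0.56, camera adjusted p = 1.7e-05, and adjusted p = 0.191 with an estimated correlation), with 2 risen without control 15 or control 19 and 0 without control 20 or any 1 of the UTI libraries, where the edgeR adjusted p of Chil3 was up to 0.137 and the median was 0.36 without control 20. At an unadjusted p under 0.05, 6 were higher and 1 lower. The 2 most abundant members went opposite ways without passing, Csf1r at -0.51 ± 0.23 (edgeR adjusted p = 0.407) and Lyz2 at 1.33 ± 0.28 (0.0626).

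Bst2, which encodes the antiviral membrane protein tetherin, rose by 1.69 ± 0.20 on the log2 scale (SE), from 15.8 to 51.1 CPM, Ifit1 by 2.25 ± 0.29 and Ifi44 by 1.24 ± 0.16. Of 27 tested interferon-stimulated genes, 7 rose and 0 fell, and 18 rose when adjusted over the list alone (median 0.91, camera adjusted p = 6.29e-21, and adjusted p = 0.0598 with an estimated correlation). Isg15 had 2.31 ± 0.72 and Usp18 -0.01 ± 0.49, neither past the test. The count was 12 without control 19, 1 without control 20 and 4 without UTI 14, and the calls of Ifi44 and Ifit1 ended without control 20 (edgeR adjusted p = 0.052 for both).

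Havcr1 (ENSMUSG00000040405, chromosome 11, positions 46735080 to 46779578) went from 4.49 ± 2.66 to 104 ± 41.7 CPM (SD, n = 3; edgeR adjusted p = 0.0111). Spp1, which encodes the secreted phosphoprotein osteopontin, rose from 465 ± 124 to 1827 ± 21.8 CPM, and Timp1, a metalloproteinase inhibitor gene, from 1.37 ± 1.13 to 20.2 ± 6.27 CPM. Of 18 tested tubular injury and repair genes, 7 rose and 0 fell, and 13 rose when adjusted over the list alone (median 1.07, camera adjusted p = 7.61e-22, and adjusted p = 0.0607 with an estimated correlation). The other 4 that rose were Plaur, Cdkn1a, Tnfrsf12a and Krt20, while Vim had 0.51 ± 0.20 and Sox9 0.47 ± 0.40. The count was 2 without control 20 or UTI 13, 3 without UTI 12 or UTI 14 and 4 with limma-voom. The call of Havcr1 ended without control 20 or UTI 14 (edgeR adjusted p of up to 0.0688) and that of Timp1 without any 1 of the UTI libraries (up to 0.122). Without control 20 or UTI 13 the calls of Plaur, Cdkn1a, Tnfrsf12a and Krt20 ended, as did those of Plaur, Cdkn1a and Tnfrsf12a without UTI 12, Plaur and Krt20 without UTI 14, and Cdkn1a and Krt20 without control 15 (up to 0.180).

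**Figure D2:**
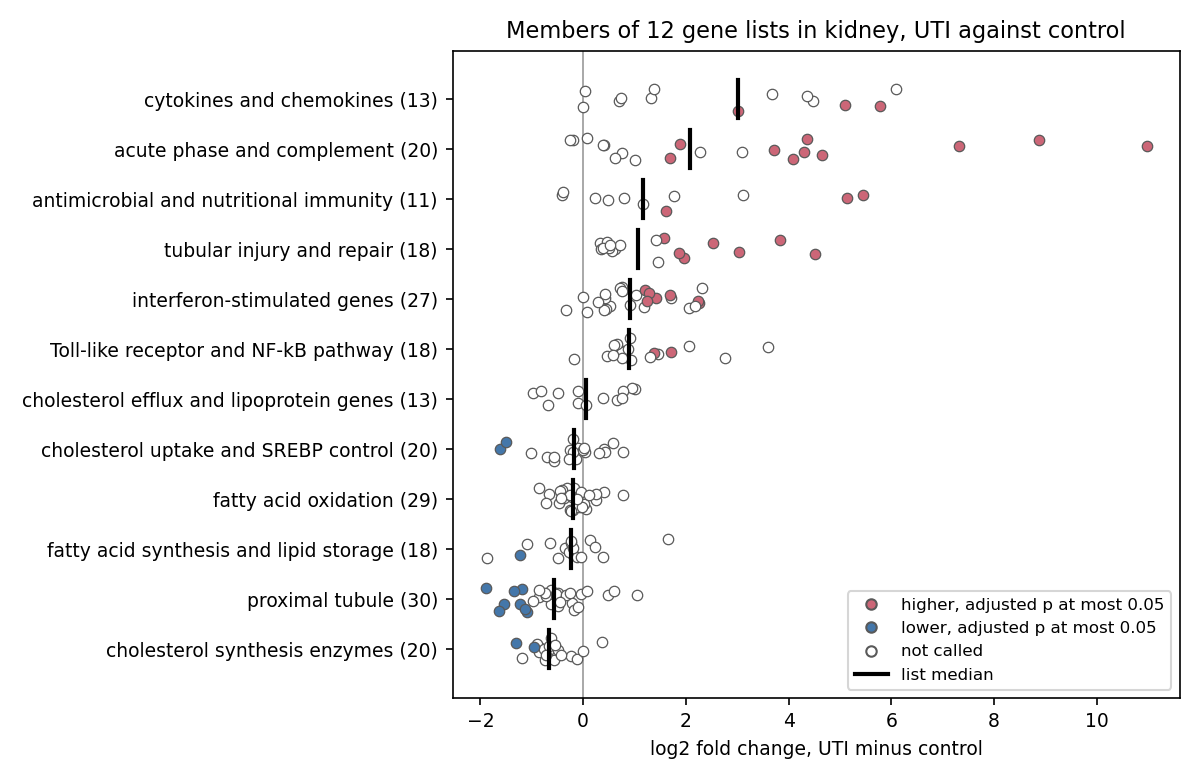
Log2 fold change, UTI minus control, of each tested member of the 12 main gene lists, with the number of tested members in brackets. Filled points passed an adjusted p of 0.05 (red, higher; blue, lower), open points did not, and black bars are list medians, from 3.02 for cytokines and chemokines to -0.67 for cholesterol synthesis enzymes.

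Nsdhl (ENSMUSG00000031349, chromosome X, positions 72918557 to 72958514), a sterol dehydrogenase gene of the late pathway, fell from 83.3 ± 6.12 to 33.6 ± 3.73 CPM (SD, n = 3; edgeR adjusted p = 0.00364). Msmo1 (ENSMUSG00000031604, chromosome 8, positions 64718139 to 64733792), a sterol methyl oxidase gene, fell from 87.4 ± 5.72 to 45.4 ± 3.77 CPM (adjusted p = 0.0154, edgeR). Of 20 tested cholesterol synthesis enzymes, 2 fell and 0 rose, and 13 fell when adjusted over the list alone, with 19 of the 20 log2 fold changes negative (median -0.67, camera adjusted p = 6.76e-13, and adjusted p = 0.0607 with an estimated correlation). Sqle had -0.12 ± 0.17 and Hmgcs1 -0.24 ± 0.25. The list's score, a mean log2 deviation from the controls, was -0.49 in UTI 12, -0.79 in UTI 13 and -0.56 in UTI 14. The proximal tubule list was lower in the same libraries, with scores of -0.43, -0.76 and -0.45 and a median of -0.57. The count was 6 without control 19 and 1 without control 20 or any 1 of the UTI libraries, where the call of Msmo1 ended (adjusted p of up to 0.11, edgeR).

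Among 20 tested genes of cholesterol uptake and its control by the SREBP transcription factors, 2 fell, Insig1 among them, and 0 rose. Insig1 (ENSMUSG00000045294, chromosome 5, positions 28071363 to 28078662), which encodes a sterol-regulated anchor of the SREBP pathway, went from 25.1 ± 1.86 to 8.90 ± 1.87 CPM (SD, n = 3; edgeR adjusted p = 0.00949). Lipa had -1.02 ± 0.22 (SE; edgeR adjusted p = 0.0534) and Srebf2 -0.25 ± 0.16 (0.604). With 5 that fell when adjusted over the list alone, the list had a median of -0.17, or -0.05 with library totals alone (camera adjusted p = 0.00636, and adjusted p = 0.13 with an estimated correlation). The count was 5 without control 19, 0 without control 20, UTI 13 or UTI 14, and 1 without UTI 12 or with limma-voom. The call of Insig1 ended without control 20, UTI 13 or UTI 14 (edgeR adjusted p of up to 0.0662).

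Of 13 tested genes of cholesterol efflux and lipoproteins, 0 were called by edgeR, 2 rose and 3 fell when adjusted over the list alone, and DESeq2 called 1 higher and 1 lower (median 0.06, camera adjusted p = 0.868). At an unadjusted p under 0.05, 2 were higher and 4 lower. Abca1, a cholesterol exporter gene, had 1.003 ± 0.213 (SE; edgeR adjusted p = 0.0549), Apoe -0.48 ± 0.17 (0.242), Apob -0.98 ± 0.24 (0.104) and Apom -0.82 ± 0.24 (0.155). Without control 19, 2 rose and 1 fell, without control 15, 1 fell, and without a low-count filter, 2 rose and 2 fell. Of the same genes, 1 rose with library totals alone, with totals without the 50 most abundant genes, under the stricter filter or after thinning. The median lay between 0.03 (without UTI 13) and 0.25 (without UTI 12) with 1 library left out and was -0.08 under the stricter filter, -0.01 after thinning, 0.18 with library totals alone, 0.37 in DESeq2 and 0.50 without a low-count filter.

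Scd1, which encodes the desaturase that makes monounsaturated fatty acids, fell from 523 ± 52.4 to 224 ± 10.7 CPM (SD, n = 3; edgeR adjusted p = 0.00428). It was the 1 of 18 tested genes of fatty acid synthesis and lipid storage that fell, with 0 risen, and 4 fell and 1 rose when adjusted over the list alone (median -0.23, or -0.10 with library totals alone, camera adjusted p = 0.0043, and adjusted p = 0.1 with an estimated correlation). Fasn had -1.09 ± 0.26 and Plin4 1.65 ± 0.48, neither past the test. The count was 2 fallen without control 20, and 1 fallen and 1 risen without control 19, and the median was -0.15 without control 15. The adipocyte markers were lower beside this list, with 1 of 7 fallen and a median of -0.58 (camera adjusted p = 0.000273, and adjusted p = 0.0801 with an estimated correlation). Of 29 tested fatty acid oxidation genes, 0 rose and 0 fell in edgeR, 6 were lower at an unadjusted p under 0.05, 3 fell when adjusted over the list alone and DESeq2 called 1 lower. Acaa1b had -0.85 ± 0.20, Ppara -0.72 ± 0.20 and Acaa2 -0.67 ± 0.19, and the list had a median of -0.19, or -0.06 with library totals alone (camera adjusted p = 0.024, and adjusted p = 0.538 with an estimated correlation). That list was not called without control 15 (camera adjusted p = 0.0547) or without UTI 13 (0.364), and 2 of its genes fell without control 19 and 3 without a low-count filter. Its median was -0.11 without control 19, -0.31 without UTI 12 and -0.13 without UTI 13.

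**Figure D3:**
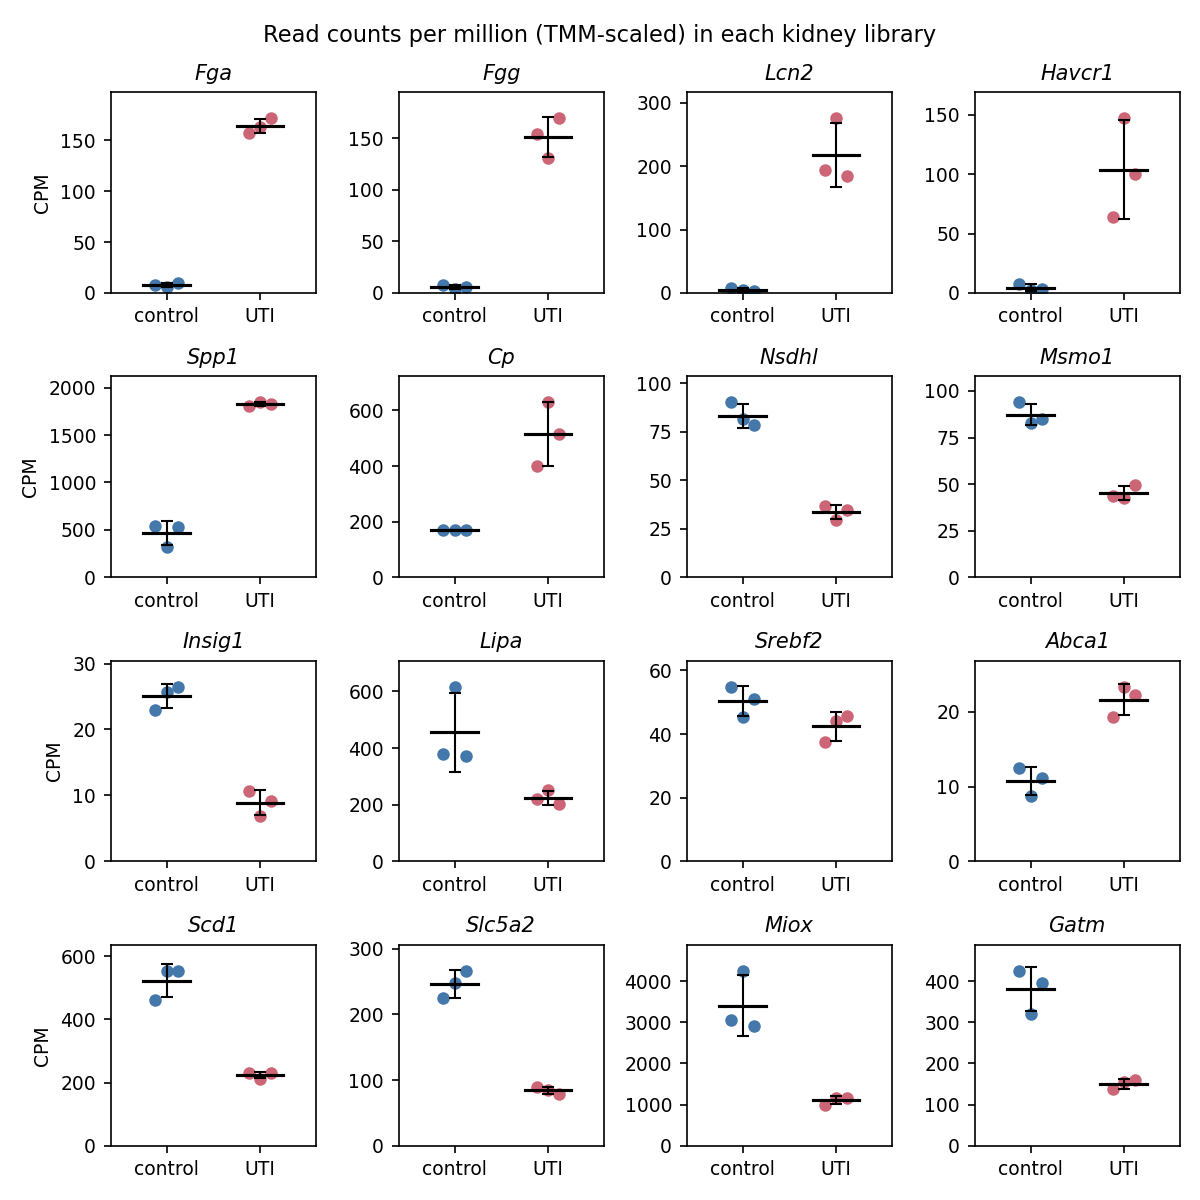
TMM-scaled CPM of 16 genes, each point a kidney library (blue, control; red, UTI), with the group mean as a horizontal bar and the SD as an error bar (n = 3). Fga went from 7.99 to 164 CPM and Nsdhl from 83.3 to 33.6 CPM with no overlap, while Srebf2, at 50.5 and 42.4 CPM, overlapped.

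Slc5a2 (ENSMUSG00000030781, chromosome 7, positions 128265657 to 128272430), which encodes the glucose transporter SGLT2, went from 246 ± 20.7 to 84.3 ± 5.49 CPM (SD, n = 3; edgeR adjusted p = 0.00103). Miox (ENSMUSG00000022613, chromosome 15, positions 89334398 to 89337015), the myo-inositol oxygenase gene, went from 3409 ± 732 to 1104 ± 96.3 CPM, and Gatm, the first enzyme of creatine synthesis, from 380 ± 53.3 to 150 ± 11.7 CPM. Of 30 tested proximal tubule genes, 8 fell and 0 rose, and 15 fell when adjusted over the list alone (median -0.57, camera adjusted p = 7.82e-20, and adjusted p = 0.0607 with an estimated correlation). The phosphate transporter genes Slc34a1 (-1.09 ± 0.17) and Slc34a3 (-1.90 ± 0.27) were among those that fell, while Napsa (-0.10 ± 0.16) and Slc27a2 (-0.17 ± 0.15) did not pass. Other genes that fell were Inmt (-1.71 ± 0.18), Dpep1 (-1.56 ± 0.23), Cela1 (-1.49 ± 0.18) and Dbp (-1.74 ± 0.26). The count was 12 without control 19, 4 without control 20 or UTI 14 and 5 without UTI 12. The call of Slc34a1 ended without control 20 or any 1 of the UTI libraries (edgeR adjusted p of up to 0.113), Slc34a3 without control 20, UTI 12 or UTI 14 (0.0562), Dpep1 without UTI 12 or UTI 13 (0.0829), Dbp without control 20, UTI 13 or UTI 14 (0.116) and Sectm1b without control 20 (0.0604).

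Of 15 tested genes of the loop of Henle and distal tubule, the calcium-binding protein genes Calb1 (-1.33 ± 0.20) and Pvalb (-1.48 ± 0.27) fell and 0 rose, with 4 fallen when adjusted over the list alone (median -0.25, or -0.11 with library totals alone, camera adjusted p = 9.01e-05, and adjusted p = 0.0663 with an estimated correlation). Umod, which encodes the urinary protein uromodulin, had 0.32 ± 0.20 from 1033 ± 204 to 1294 ± 226 CPM (SD, n = 3; edgeR adjusted p = 0.582), and Slc12a1 had -0.52 ± 0.19. The count was 0 without control 20 or UTI 12, 1 with limma-voom or without control 15, UTI 13 or UTI 14, and 3 without control 19. The edgeR adjusted p of Calb1 was up to 0.0722 and that of Pvalb up to 0.165 in the fits that ended their calls. Of 15 collecting duct genes, 1 fell, the anion exchanger gene Slc4a1 (-1.08 ± 0.20), and 0 rose (median 0.08, camera direction down, adjusted p = 0.812), with 1 risen and 1 fallen when adjusted over the list alone, and its call ended with library totals alone and without control 20 or any 1 of the UTI libraries (edgeR adjusted p of up to 0.193). The list median lay between -0.02 (without control 19) and 0.24 (without control 20) with 1 library left out. Aqp2 had 0.72 ± 0.21 (edgeR adjusted p = 0.158) and Hsd11b2 -0.17 ± 0.17, neither past the test.

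No podocyte (10 tested), endothelial (14), fibroblast and mural (12), T and NK cell (3) or B and plasma cell (4) marker was called by edgeR with its low-count filter or by DESeq2. Without that filter edgeR called 1 fibroblast and mural and 2 B and plasma cell markers lower. At an unadjusted p under 0.05, 2 endothelial markers were higher, and 3 fibroblast and mural and 2 B and plasma cell markers were lower. The most abundant members were Podxl (0.60 ± 0.62), Flt1 (0.26 ± 0.16), Ren1 (-0.16 ± 0.25), Trac (-0.20 ± 0.64) and Igkc (-1.14 ± 0.43). Next came Synpo (-0.12 ± 0.21), Plvap (0.41 ± 0.16), Dcn (-0.37 ± 0.18), Cd8a (-1.01 ± 0.52) and Ighm (-1.24 ± 0.44). Camera called none of these 5 lists (adjusted p of 0.812, 0.363, 0.113, 0.806 and 0.059). It did call the endothelial list without control 19 (0.0452), the fibroblast list without control 20 (0.00798) or UTI 14 (0.0332) or without a low-count filter (0.0398). It called the B cell list without control 15 (0.0224) or UTI 12 (0.0445) or with library totals alone (0.027).

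The uroplakin genes of the urothelium, the lining of the renal pelvis and lower tract, were at low levels, with Upk1a at 9.72 ± 5.09 CPM in controls and 1.22 ± 1.19 CPM in UTI and Upk2 at 4.51 ± 2.30 and 0.629 ± 0.397 CPM (SD, n = 3). Of 10 urothelial markers, edgeR called 0, with 4 lower at an unadjusted p under 0.05 and 4 fallen when adjusted over the list alone, and DESeq2 called 4 lower. Sprr1a and Psca, the most abundant, had 0.51 ± 0.61 and -0.00336 ± 1.20. The list had a median of -0.36 (camera adjusted p = 0.00118, and adjusted p = 0.362 with an estimated correlation), a call that ended without control 15 (0.105) or under the stricter filter (0.0897). EdgeR called 4 lower without control 19 or a low-count filter, 2 with DESeq2 size factors and 1 without UTI 13 or the 50 most abundant genes. Its median was 0.05 without control 15, -0.56 without control 19, -0.56 without control 20, -0.03 without UTI 12, -2.46 without UTI 13, -0.06 without UTI 14, 0.28 under the stricter filter, -0.21 with library totals alone, -0.77 in DESeq2 and -1.25 in limma-voom, so its sign and size varied between fits. Of 7 adipocyte markers, 1 fell, Car3, and 0 rose (median -0.58, camera adjusted p = 0.000273, and adjusted p = 0.0801 with an estimated correlation), with 2 fallen without control 19, a median of -0.96 without control 20 and -1.55 without UTI 13, -0.08 under the stricter filter, -0.38 after thinning and -1.19 without a low-count filter, while Pnpla2 had 0.03 ± 0.18. Of 7 erythroid genes 0 were called by edgeR or DESeq2 and 0 had an unadjusted p under 0.05, with Hbb-bs at 2.14 ± 1.17 and Hba-a1 at 2.03 ± 1.31. The erythroid score was 2.65 in UTI 12, -0.06 in UTI 13 and -0.14 in UTI 14 (camera adjusted p = 0.118 over all libraries, 0.00467 without UTI 13, 0.00345 without UTI 14 and 0.0321 without a low-count filter). Its median was 1.83 in edgeR, -0.18 without UTI 12 and 0.70 in DESeq2. Adrenal cortex and skeletal muscle had 2 and 1 tested members, too few for a list test, and Star, Akr1b7 and Mylpf did not pass in edgeR, where 0 had an unadjusted p under 0.05, nor in DESeq2. Without a low-count filter edgeR called 1 adrenal cortex gene lower.

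Lists that read RNA quality or cell state held 0 genes called by edgeR. The 8 mitochondrially encoded genes had a median of -0.33, with mt-Nd4 at -0.33 ± 0.21 and 1 gene lower at an unadjusted p under 0.05 (camera adjusted p = 0.0423, and adjusted p = 0.607 with an estimated correlation). That call ended without control 15, control 20, UTI 12 or UTI 13 (adjusted p of up to 0.378) or under the stricter filter (0.0625), and the median was -0.21 without control 20, -0.22 without UTI 13 and -0.20 with library totals alone. The 13 immediate early and heat shock genes had a median of 0.61 (0.92 without control 15 and 0.40 without UTI 13), with 4 higher at an unadjusted p under 0.05 and 3 risen when adjusted over the list alone (camera adjusted p = 0.000555, and adjusted p = 0.328 with an estimated correlation). Cytosolic ribosomal protein genes (median 0.10, camera adjusted p = 0.484), glycolysis and hypoxia genes (0.08, 0.766) and proliferation genes (0.06, 0.806) were not called as lists, and 1 higher and 1 lower of these genes, both in the glycolysis list, had an unadjusted p under 0.05. With 1 library left out their medians lay between 0.03 (without control 19) and 0.21 (without control 15), -0.05 (without UTI 14) and 0.18 (without control 20), and -0.16 (without UTI 13) and 0.29 (without UTI 12). Rplp1 had 0.10 ± 0.16, Rpl32 0.15 ± 0.16, Ndrg1 0.36 ± 0.17, Aldoa -0.19 ± 0.17, Pcna 0.17 ± 0.26 and Tyms -0.23 ± 0.20. Hspa8 had 0.16 ± 0.15, Hsph1 0.46 ± 0.18 and mt-Cytb -0.04 ± 0.44. DESeq2 called 2 immediate early and heat shock genes and 1 glycolysis and hypoxia gene, all higher. EdgeR called 1 immediate early and heat shock gene higher without control 15 or control 19, and 2 glycolysis and hypoxia genes higher without control 19. Without a low-count filter it called 3 and 1 of these genes higher and 1 mitochondrially encoded gene lower.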

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

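Thinning was chosen after the results were seen, and the other alternatives were planned. No paired analysis was possible because the library numbers in the titles have none in common and the numbering from 1 to 3 in a deposited table follows list order only; that numbering was not tried as a block. None of the 157 called genes changed sign under any alternative run. Of 700 alternative values of the 39 called named genes, 620 stayed past the threshold and 80 did not, and of 904 of the 51 others, 46 passed it. DESeq2 size factors gave 165 genes, totals without mitochondrial genes 157, totals without the 50 most abundant genes 159, the stricter filter 134, limma-voom 134, edgeR without the robust option 139 and thinning to the smallest library 169, of which 150 were among the 157. Library totals alone gave 142 genes, 48 of them lower and 66.2% higher, since they move the median gene up by 0.135. Without a low-count filter 624 genes were called (287 higher, 337 lower) and with DESeq2 345 (160 and 185), each with all 157, and the cause was not tested. A minimum change of 1 on the log2 scale left 20 (18 and 2, 90% higher) and an adjusted p of 0.01 left 51 (30 and 21), as stricter thresholds do. With 1 library left out, the count ranged from 33 (without control 20) to 506 (without control 19), the higher genes from 20 to 222, the lower from 13 to 284 and the percent higher from 43.9 to 70.7 (without UTI 14). The fits without UTI 12, UTI 13 and UTI 14 gave 53, 46 and 58, and without control 15 154. Fewer libraries lower the power of each fit, and the cause of the rise without control 19 is open.

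Of 18 called lists, 2 held with an estimated correlation and 11 with fry. The estimated-correlation adjusted p was 0.0607 for cholesterol synthesis, tubular injury and proximal tubule, 0.0598 for cytokines and interferon-stimulated genes, 0.0635 for the Toll-like receptor and NF-kB list, 0.0551 for antimicrobial genes, 0.13 for cholesterol uptake, 0.1003 for fatty acid synthesis and 0.538 for fatty acid oxidation. These estimates allow for genes of a list that vary together, which can lower the power of the test. The neutrophil list had an estimated correlation of -0.047, under the preset 0.01, yet its camera p went from 1.9e-14 to 0.00137. Varying together is thus not the reason for every weaker p. With an estimated correlation, camera also uses the residual degrees of freedom of the 6 libraries, far fewer than with the preset one. This alone weakens p, and how much of each change it explains was not tested. With fry, the adjusted p was 0.343 for fatty acid oxidation and 0.0822 for fatty acid synthesis. The fatty acid oxidation list had 0.0625 under the stricter filter and from 0.000871 (without UTI 12) to 0.364 (without UTI 13) with 1 library left out, so its call depends on these choices, and the cause was not tested. Depth limits genes near the floor, such as Il6 with 8 reads over the UTI libraries, and at this replication the simulated 2-fold changes were recovered in 37 of 100 genes. Of list members, DESeq2 and edgeR without a low-count filter called lower 3 and 9 for cholesterol synthesis, 4 and 4 for uptake (with 1 higher in the latter), 3 and 4 for fatty acid synthesis (1 higher in the latter), 12 and 14 for proximal tubule and 3 and 4 for loop and distal tubule. They called higher 9 and 10 cytokines, 3 and 7 Toll-like receptor and NF-kB genes, 4 and 5 antimicrobial genes, 9 and 13 interferon-stimulated genes, 8 and 10 injury genes and 2 and 3 monocyte and macrophage markers. Library totals alone moved list medians toward higher values, with the median of all genes. Against a minimum change of 1, edgeR called 7 acute phase, 2 injury, 1 antimicrobial, 1 neutrophil and 1 adipocyte gene and 0 in the other lists fixed beforehand. At an adjusted p of 0.01 it called 1 injury, 1 cytokine, 4 interferon-stimulated and 1 cholesterol synthesis gene, beside genes of further lists such as Fga, Lcn2 and Slc5a2.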

Other observations

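The 7 gene lists on the clock, phosphate, arginine, metallothionein, carbonic anhydrase, hepatocyte acute phase and hepatocyte constitutive genes, the thinning and the neutrophil test were chosen after the results were seen, and the other tests were written after the called genes were known but before their own values. Several of the 7 lists were built around genes already seen to change, so their p-values are not independent evidence. Usp2, a clock output gene, fell from 316 ± 52.2 to 121 ± 10.4 CPM (SD, n = 3; edgeR adjusted p = 0.00364), and Dbp (-1.74 ± 0.26), Tef (-1.07 ± 0.17) and Hlf (-1.06 ± 0.16, log2 ± SE) also fell, the 4 of 17 tested clock genes that were called, with 0 risen (median -0.60, camera adjusted p = 6.41e-07, and adjusted p = 0.0172 with an estimated correlation). Arntl, whose product drives the clock, had 1.75 ± 0.47 (edgeR adjusted p = 0.123). The calls of Tef and Hlf ended without control 20 or any 1 of the UTI libraries (up to 0.113 and 0.0798) and that of Dbp without control 20, UTI 13 or UTI 14 (up to 0.116). The clock count was 7 without control 19, 2 without UTI 12 and 1 without control 20, UTI 13 or UTI 14, the median was -0.36 without control 15, and the labels give no time of day of harvest.

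Among 12 genes of phosphate handling, the transporter gene Slc34a2 rose from 1.07 ± 0.689 to 17.8 ± 5.25 CPM while Slc34a1 and Slc34a3 fell (median -0.40, camera adjusted p = 0.0395, and adjusted p = 0.115 with an estimated correlation). That list call ended without control 15 (0.217), UTI 13 (0.108) or UTI 14 (0.0524), and 4 fell without control 19. The call of Slc34a1 ended without control 20 or any 1 of the UTI libraries (up to 0.113) and that of Slc34a3 without control 20, UTI 12 or UTI 14 (up to 0.0562). Both arginase genes rose, Arg1 with 3 reads over the controls and 140 over the UTI libraries, a ratio of 60.7 with a 95% counting interval of 20.3 to 298, and Arg2 by 2.07 ± 0.33 from 17.9 ± 8.26 to 75.5 ± 3.04 CPM, while Ass1 (-1.13 ± 0.16) and Gatm fell (9 arginine and polyamine genes, median -0.08, mean 0.45, camera direction down, adjusted p = 0.16). The call of Arg1 ended without UTI 13 (0.0527), that of Arg2 without control 20 or any 1 of the UTI libraries (up to 0.171) and that of Ass1 without control 20 or UTI 12 (up to 0.0654). Of 12 metallothionein and glutathione genes, Gclc (1.23 ± 0.15) and Mt2 (1.33 ± 0.18) rose and 0 fell (camera adjusted p = 0.000118, and adjusted p = 0.0862 with an estimated correlation), both calls ended without control 20 (0.052 and 0.0598), and 1 fell without control 19. Of 10 carbonic anhydrase and acid handling genes, 1 fell, Car3, with 4 without control 19, and 0 rose (camera adjusted p = 5.14e-06, and adjusted p = 0.0669 with an estimated correlation).

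Fibrinogen and serum amyloid A genes, best known from liver, rose in these kidneys, and 8 of 10 genes of a hepatocyte acute phase list did so (median 4.33, camera adjusted p = 1.28e-138, and adjusted p = 8.38e-05 with an estimated correlation). RNA from liver would bring albumin, but the 13 tested of 20 constitutive hepatocyte genes had a median of 0.0843 with 0 risen, 3 higher and 2 lower at an unadjusted p under 0.05, and 1 fallen, Ttr, not called without control 20 or any 1 of the UTI libraries (edgeR adjusted p of up to 0.159; camera adjusted p = 0.979). Without 1 library that median lay between -0.137 and 0.198, with 1 risen and 2 fallen without control 15 and 2 risen and 2 fallen without control 19, and Alb was at 5.58 CPM in controls and 4.25 CPM in UTI against 164 CPM for Fga. Neutrophil RNA would bring more S100a8 and S100a9 than Fga, but together they reached 0.519 of its CPM. Their 85.3 CPM in UTI also lay below Fgg (152 CPM), but above Fgb (76.9 CPM) and Saa1 (74.9 CPM). For acute phase genes less abundant than S100a8 and S100a9 together the comparison therefore does not decide. If depth alone made these calls thinning would end them, but 10 of the 10 acute phase calls were kept after thinning to the smallest library. Expression by kidney cells after infection may remain as a hypothesis, found and tested on the same data, and RNA of infiltrating cells stays open for the less abundant acute phase genes.

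Of 30 proximal tubule genes 8 fell and 0 rose (adjusted p = 0.0607 for the list with an estimated correlation), and 3 technical or cellular causes were examined. A smaller share of proximal tubule cells alone would lower all members alike if all were made evenly and solely by these cells. Their log2 fold changes differed more than their standard errors allow (Cochran's Q 209.9 on 29 degrees of freedom, n = 30 members, p = 2.53e-29, an approximation that treats genes as independent). The whole 95% interval lay above the weighted mean of -0.74 for 7 members and below it for 8. Members need not be expressed alike in all proximal tubule cells, so the test does not decide on a loss of part of these cells. All 8 calls were kept after thinning to the smallest library, and without control 19 the median was -0.66 with 8 of 8 calls kept. The list's score was lower in control 19 (-0.30) than in control 15 and control 20 (0.15 each). Control 19 thus lay on the side of the UTI libraries (-0.43, -0.76 and -0.45) and lessened the fall, so leaving it out was bound to deepen it. These scores argue against control 19 alone having made the fall. A loss of part of the proximal tubule cells, alone or together with regulation of single genes, stays open and was not tested.

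Control 19 stood apart from the other controls, and leaving it out raised the calls from 157 to 506. Across genes, its log ratio to the other controls had a Spearman correlation of -0.0325 with transcript length, which argues against a length trend. Its correlation with GC content was 0.139. That of control 20 was larger in size, -0.164, which by the rule written beforehand would speak against GC content. This comparison was not used, because the references of the other controls hold control 19 and give no benchmark. GC content therefore stays open. A piece with less medulla would put both the loop and collecting duct lists below the proximal tubule list, but the higher of them lay 0.511 above it. The reverse, a piece with less cortex, was not tested. Its immediate early (-0.67), ribosomal (-0.57), proximal tubule (-0.45) and collecting duct (-0.34) lists were below the other controls. Its loop and distal tubule (0.06) and endothelial (0.14) lists were above them. The score of the mitochondrially encoded list was -0.56 in control 19, against 0.15 in control 15 and 0.41 in control 20. The design names no difference between controls, no biological explanation was tested, and RNA quality may remain among the open causes.

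With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. The real split, 1 of the 10, called 157 genes and the highest other split 0 (edgeR).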
